A study of Oryctolagus cuniculus with 35 samples.

How the data were processed

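Lung messenger RNA was sequenced from 35 New Zealand rabbits in 5 groups of 7, with 1 library per rabbit. Per the labels' protocols, stranded libraries were read from 1 end over 75 bp on a NextSeq500, demultiplexed with bcl2fastq2 2.18.12 and trimmed with Cutadapt 1.15, and trimmed reads of over 10 bp were kept. Per the submitters' processing notes, TopHat2 2.1.1, featureCounts 1.5.2 and DESeq2 1.24.0 were used, with no role or order given for them. The genome build and the annotation are not given in the sources used here.

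The authors deposited a table for each of 4 comparisons, over 23669 Ensembl rabbit genes, of which 16304 carry a symbol. Per the file headers, each table gives a log2 fold change with its standard error on the log2 scale, a Wald statistic (a score) and a p-value with its adjusted p-value from the authors' DESeq2 comparison. Beside these, each table holds the deposited signal of 14 libraries, which per the file headers is the number of reads per gene divided by the size factor of the library. The size factors differ from table to table. Every value in these columns was a whole multiple of the lowest nonzero value of its column, within a relative tolerance of 1e-06, so that the whole reads per gene could be recovered. The 14 libraries that stand in more than 1 table gave identical recovered reads in each. Fold changes are given so that a positive value means higher with disease or with the added treatment.

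Recovered reads per library ranged from 7567008 to 33209729, with a median of 11137017, and 11104 to 12017 genes per library had at least 1 read. No pair of libraries of a group had nearly equal counts: the lowest chi-square per degree of freedom between 2 libraries was 39.4, where copies of 1 library would give about 1. A total of 10217 genes, 6140 of them with a symbol, were listed at 0 in all 35 libraries and could not be tested. Among these were all 13 protein-coding genes of the mitochondrial genome.

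The comparisons, the test for each kind of deposited value, the thresholds, the 30 gene lists, the rule for naming genes and a first set of alternatives were chosen before the data were examined. For normalized values the test chosen was limma 3.58.1 in R 4.3.3 on log2(value + 1) with an intensity trend, applied in each table to the 2 groups compared with no covariate. Genes with a value of at least 10 in at least 7 of the 14 libraries were tested, two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists with at least 3 tested members were tested by limma's camera, two-sided, with a preset correlation between genes of 0.01 and with an adjustment over the lists of a comparison. camera was run again with a correlation estimated from the residuals. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

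The genes named are, for each comparison, the 5 with the largest rise and the 5 with the largest fall among called genes with a symbol and a mean of at least 50 normalized reads, or all of these where 10 or fewer passed. To these were added the 2 members with the lowest p of each list that passed its test, and a panel of 10 genes (IL1B, IL6, CXCL8, TNF, IL10, S100A8, SFTPC, PPARGC1A, MFN2, PINK1) whatever their result. Further list members are given as values, and some genes that the rule names are not reported here. Of the panel, 7 genes could be tested and 3 could not.

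The difference between the MSC effect with and without ceftaroline was tested per gene, two-sided, as the difference of the 2 limma estimates over the root of the sum of their squared standard errors. Effects of comparisons that share the NaCl libraries were related by Spearman's correlation and covariance across genes, which are not independent replicates. The values of 1000 simulated pairs of unchanged groups sharing their controls were set beside these, and the relations were computed again for 70 splits of the 7 NaCl libraries that gave each comparison its own. The simulated groups were all drawn from residuals pooled over the real groups, so they had equal spread.

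The limma and edgeR gene tests of the 4 comparisons were tried on simulated data with 200 changed genes, 50 for each of 4 sizes of change. The test of the difference between the MSC effects and the permutation test of the score described below were not tried in this way. At a log2 change of 1, limma recovered 21 of 50 in the comparison with healthy (9545 genes), 13 of 50 for MSC (9446 genes), 17 of 50 for ceftaroline (9614 genes) and 21 of 50 for ceftaroline plus MSC (9924 genes). At a log2 change of 2 it recovered 45, 40, 47 and 46 of 50 in the same comparisons. False calls were 3 of 121, 3 of 104, 10 of 123 and 6 of 125. Each gene was drawn independently of the others, so these numbers hold for that setting. They may differ where genes vary together or where more genes change.

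Alternatives chosen before the data were examined were adjusted p thresholds of 0.01 and 0.1, a log2 fold change of at least 1, no filter on low values, pseudocounts of 0.5 and 5, each library left out in turn, a replicate block by the number in the sample title, and leaving out the NaCl library whose description carries the S00 mark of the healthy libraries. Others used the authors' deposited DESeq2 statistics, with their adjusted p, with an adjustment over other sets of genes, against a t distribution with 12 degrees of freedom and against an empirical null. For lists these were the estimated correlation, a test on ranks and a minimum mean of 50 normalized reads. Alternatives chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood on the recovered reads), TMM scaling, the use of a 2-letter title ending (PD or PG) to select libraries or as a covariate, leaving out the 2 healthy libraries titled with D, joint interaction fits over the 4 pneumonia groups, separate NaCl libraries for comparisons that share them, and list tests with the block, the title ending or the S00 library. Of the joint interaction fits, an edgeR interaction term had been named beforehand for counts of all 4 groups in 1 normalization. The deposited values are scaled per table, so the difference of 2 estimates was used, and the edgeR fit on recovered reads was added later. The meaning of the title endings and of the S00 mark is not given in the sources used here. The tables were read with the R package data.table, version 1.17.8.

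A score from 0 (healthy) to 1 (pneumonia with NaCl) was computed for each library by projection on the difference between the 2 group means, each library left out of its own group's mean, after joint TMM scaling of the recovered reads. Differences in mean score were tested by exact permutation over all 3432 splits of 14 libraries, two-sided, with an adjustment over 3 comparisons. Gene order along chromosomes was taken from the mOryCun1.1 assembly annotation, in which 12476 of the 13765 symbols looked up were found. It was used only for names and neighbours. Other splits of the libraries were drawn 100 times for each comparison, the real split included.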

Results

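Lung messenger RNA was measured by sequencing in 5 groups of 7 rabbits. Healthy rabbits received saline only. The other groups had pneumococcal pneumonia with adverse mechanical ventilation and were given, 4 h after inoculation of the bacteria, saline (NaCl), human umbilical cord-derived mesenchymal stromal cells (MSC, infused cells used as a treatment), ceftaroline (a cephalosporin antibiotic, 20 mg/kg) or both. Lung pieces were taken at autopsy 24 h after inoculation or at an earlier death. Recovered reads per library ranged from 7567008 to 12794413 in healthy, from 7611988 to 14948358 in NaCl, from 9642813 to 11987726 in MSC, from 11499403 to 33209729 in ceftaroline and from 11137017 to 18271138 in ceftaroline plus MSC. A 2-letter ending of the sample title (PD or PG) marks 5 healthy (4 PD and 1 PG), 3 NaCl and 2 MSC libraries (all PG) and none of the others. In the NaCl and MSC groups, titles with the ending also begin with other letters than the rest, so ending and letter change together. Of the panel of 10 genes, SFTPC (surfactant protein C, ENSOCUG00000002024) and MFN2 (a protein of mitochondrial fusion, ENSOCUG00000007972) were listed at 0 in all 35 libraries. PPARGC1A, a coactivator of mitochondrial biogenesis (ENSOCUG00000014668), had 1 to 23 reads per library and was under the minimum for testing.

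Pneumonia with ventilation was set against healthy lung to ask how infection and ventilation together, called disease here, alter lung transcripts. The S00 mark in the library descriptions, whose meaning is not given, stands on all 7 healthy libraries and on 1 NaCl library. What it marks thus differs nearly as the groups do, and leaving out that NaCl library cannot tell the mark and the disease apart. IL6, an early cytokine of acute inflammation (ENSOCUG00000027471), rose from 2.73 ± 2.13 to 17313 ± 13961 normalized reads (SD, n = 7 each), a log2 fold change of 11.82 (SE 0.65, adjusted p = 5.0e-09). CXCL8, a chemokine that draws neutrophils (ENSOCUG00000011835), rose from 78.4 ± 20.4 to 74288 ± 79518, a log2 fold change of 9.20 (SE 0.54, adjusted p = 7.9e-09). SLC34A2, the phosphate transporter of alveolar type II cells, fell from 15697 ± 3957 to 1549 ± 1440 (log2 fold change -3.83, SE 0.46, adjusted p = 4.7e-06). PINK1, the kinase that marks damaged mitochondria for removal, fell from 6040 ± 1057 to 1686 ± 717 (log2 fold change -1.94, SE 0.24, adjusted p = 6.0e-06). All 7 NaCl libraries lay beyond the healthy mean in the direction given for these 4 genes.

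The other large rises were those of CSF3, the growth factor of granulocytes, by 9.47 on the log2 scale (SE 0.80, adjusted p = 1.6e-07), ADAMTS4, a protease that cleaves matrix proteoglycans, by 9.39 (SE 0.40, adjusted p = 1.3e-09), and CCL4, a chemokine for monocytes and T cells, by 8.28 (SE 0.90, adjusted p = 1.8e-06). ADAMTS4 had 33.9 ± 16.8 normalized reads in healthy and 25706 ± 13912 in NaCl lungs (SD, n = 7 each). Large falls were those of AQP8, a water and peroxide channel (-6.17, SE 0.66, adjusted p = 1.6e-06), GLIS1, a zinc-finger transcription factor (-5.92, SE 0.40, adjusted p = 2.8e-08), SLC6A2, the noradrenaline transporter that lung endothelium also carries (-4.87, SE 0.75, adjusted p = 4.5e-05), and TMEM35A, a chaperone of acetylcholine receptors (-4.81, SE 0.64, adjusted p = 1.1e-05). In the panel, IL1B (an inflammasome-released cytokine) rose by 4.94 (SE 0.58, adjusted p = 3.9e-06), TNF by 4.34 (SE 0.72, adjusted p = 9.2e-05), S100A8 (a subunit of the neutrophil protein calprotectin) by 4.41 (SE 0.45, adjusted p = 8.9e-07) and IL10, a cytokine that restrains inflammation, by 4.12 (SE 0.63, adjusted p = 4.5e-05).

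Of 9545 genes tested by limma, 5788 passed, 2836 higher and 2952 lower with disease, and 6120 had an unadjusted p under 0.05 where 477 would by chance. edgeR called 5790, of which 5604 were shared, and the authors' deposited table lists 6570. Of the called genes, 3400 had a log2 fold change of at least 1 in size and 2851 had no overlap between the 7 healthy and the 7 NaCl libraries. In libraries without a title ending (healthy replicates 1 and 5 and NaCl replicates 1 to 4), 3764 genes passed. In those with it (5 healthy and 3 NaCl) 5496 passed, and with the ending as a covariate 5678. Both endings were treated as 1 mark, though healthy has 4 PD and 1 PG and NaCl 3 PG. The libraries with an ending were thus not matched on the same ending. IL6 rose by 11.28 without the ending and by 12.20 with it, and PINK1 had a log2 fold change of -1.60 without it and -2.42 with it.

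**Figure D1:**
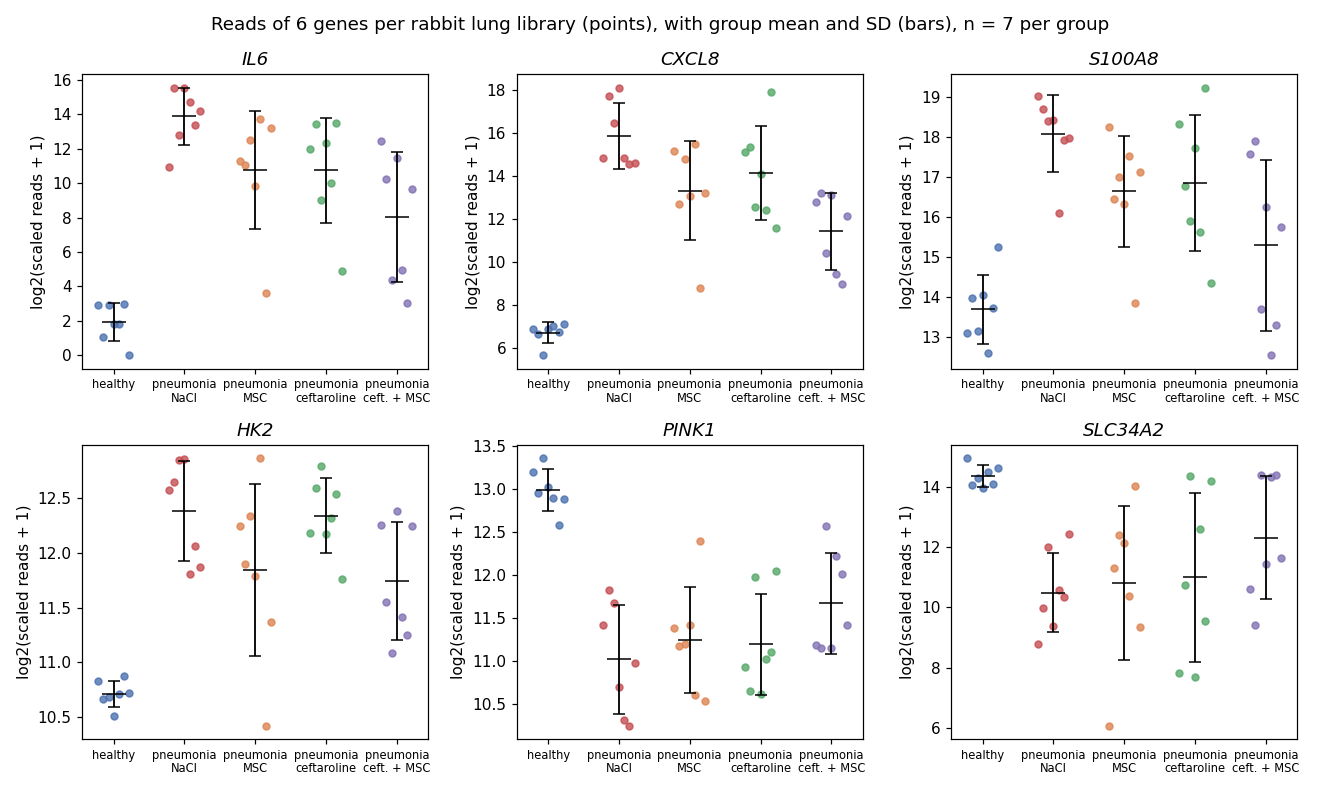
Each point is 1 library of IL6, CXCL8, S100A8, HK2, PINK1 or SLC34A2 in the 5 groups, as log2 of jointly TMM-scaled reads plus 1, with bars for the mean and SD of 7 libraries. The mean of IL6 was 1.92 in healthy, 13.88 in NaCl, 10.75 in MSC, 10.74 in ceftaroline and 8.03 in ceftaroline plus MSC, and that of PINK1 was 12.99, 11.02, 11.25, 11.19 and 11.68 in the same order.

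Of 29 gene lists tested in the comparison with healthy, 6 ranked higher and 2 lower with disease by camera. Inflammatory cytokines had 20 of 22 tested members higher and none lower past the threshold, over all genes and adjusted over the list alone (adjusted p = 1.1e-09; adjusted p = 0.441 with an estimated correlation). All 10 tested glycolysis genes rose, among them PKM, the pyruvate kinase, by 3.41 (SE 0.33) and HK2, the inducible hexokinase, by 1.69 (SE 0.17). For this list the adjusted p was 0.000510, and the adjusted p = 0.509 with an estimated correlation. Neutrophil markers had 9 of 10 higher and 1 lower (adjusted p = 0.000732; adjusted p = 0.485 with an estimated correlation), led by CAMP, an antimicrobial granule peptide (7.51, SE 0.64), and IL1R2, a decoy receptor for IL-1 (6.05, SE 0.57). The stress response had 7 of 8 higher (adjusted p = 0.00178; adjusted p = 0.441 with an estimated correlation), with CHAC1, a glutathione-degrading enzyme, at 3.23 (SE 0.29) and ASNS, the asparagine synthetase, at 1.79 (SE 0.20). Interferon-induced genes had 11 of 15 higher (adjusted p = 0.00814; adjusted p = 0.620 with an estimated correlation), with the antiviral IFIT5 at 2.60 (SE 0.37) and the RNA sensor DDX58 at 2.40 (SE 0.38). Genes of resolution and repair had 9 of 12 higher and 3 lower (adjusted p = 0.0123; adjusted p = 0.230 with an estimated correlation), with TNFAIP6, a hyaluronan-binding protein, at 6.22 (SE 0.50) and IL4R at 2.23 (SE 0.18). In each of these 6 lists the counts adjusted over the list alone were the same as over all genes.

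Both lists of alveolar epithelium ranked lower. Type I cell markers had 7 of 8 members lower (adjusted p = 0.0270; adjusted p = 0.582 with an estimated correlation), among them EMP2, a membrane protein of these cells (-2.06, SE 0.29), and RTKN2 (-1.91, SE 0.40). The 3 tested markers of type II cells all fell (adjusted p = 0.0470; adjusted p = 0.485 with an estimated correlation). They were SLC34A2, the transcription factor ETV5 (-1.19, SE 0.16) and the surfactant protein SFTPB (-2.01, SE 0.38). Counts adjusted over the list alone were equal to those over all genes in both lists. Without the NaCl library that carries the S00 mark of the healthy libraries, the type II list had an adjusted p of 0.0572.

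Nuclear genes of mitochondrial function went both ways. Of 21 tested nuclear genes of oxidative phosphorylation, 4 rose and 4 fell over all genes, and 2 rose and 4 fell adjusted over the list alone (adjusted p = 0.961 for the list), while in libraries without a title ending the list ranked higher (adjusted p = 0.0375). NDUFS1, a subunit of complex I, rose by 0.58 (SE 0.11), while NDUFB3, an accessory subunit, fell by 0.67 (SE 0.16). Among 10 fatty acid oxidation genes 8 fell and 1 rose, with HADH, which acts on short chains, at -1.73 (SE 0.20), ACADM, which acts on medium chains, at -1.45 (SE 0.26) and ACADVL, which acts on very long chains, at 0.69 (SE 0.18). Of 9 genes of mitochondrial biogenesis 6 rose, including PPRC1, a PGC-1 relative, by 1.77 (SE 0.23) and the DNA helicase TWNK by 0.99 (SE 0.17). These lists had adjusted p of 0.0617 and 0.0737, and list-alone counts equal to those over all genes. Mitochondrial dynamics had 4 of 8 members higher (adjusted p = 0.196), mitophagy 2 higher and 1 lower of 8 (adjusted p = 0.857), and the citric acid cycle 5 higher and 2 lower of 10 (adjusted p = 0.492). The 13 genes of the mitochondrial genome were listed at 0 and could not be tested.

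The remaining lists had an adjusted p above 0.05 in all libraries. Airway epithelium had 6 of 10 members lower, such as DNAH5, a motor of cilia, at -2.34 (adjusted p = 0.0538 for the list). Matrix genes had 7 of 10 lower and 1 higher (0.0737), with the fibroblast factor TCF21 at -2.83 and fibronectin (FN1) at 1.05. Innate sensing had 8 higher and 1 lower of 12 (0.0766), with CD14, the endotoxin coreceptor, at 2.68. Hypoxia response had 7 higher and 2 lower of 13 (0.101), with HIF1A at 2.86 and MXI1, an antagonist of MYC, at -1.31. Macrophage markers had 5 higher and 1 lower of 13 (0.196), with the haemoglobin scavenger CD163 at 3.49. Complement and coagulation had 4 higher and 1 lower of 8 (0.224), with TFPI, the tissue factor inhibitor, at 2.31. Antioxidant genes had 6 higher and 4 lower of 13 (0.376), with haem oxygenase HMOX1 at 3.64 and extracellular dismutase SOD3 at -2.97. Endothelium had 4 higher and 6 lower of 14 (0.848), with P-selectin (SELP) at 5.18 and the angiopoietin receptor TEK at -2.19. Smooth muscle had 3 of 8 lower (0.333), striated muscle 1 of 3 (0.357), T and NK cells 1 of 9 (0.794), and B and plasma cells 1 higher and 2 lower of 11 (0.961). MHC class II presentation had 2 of 10 lower over all genes and none adjusted over the list alone (0.779). Red cell markers (0.779) and the cell cycle (0.873) had none of 6 and none of 16 members past the threshold. In libraries without a title ending (healthy replicates 1 and 5 and NaCl replicates 1 to 4) 13 lists passed. They were the 8 lists above, oxidative phosphorylation, innate sensing (0.0163) and the hypoxia response (0.0177), which ranked higher, and smooth muscle (0.000603) and matrix genes (0.00996), which ranked lower.

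**Figure D2:**
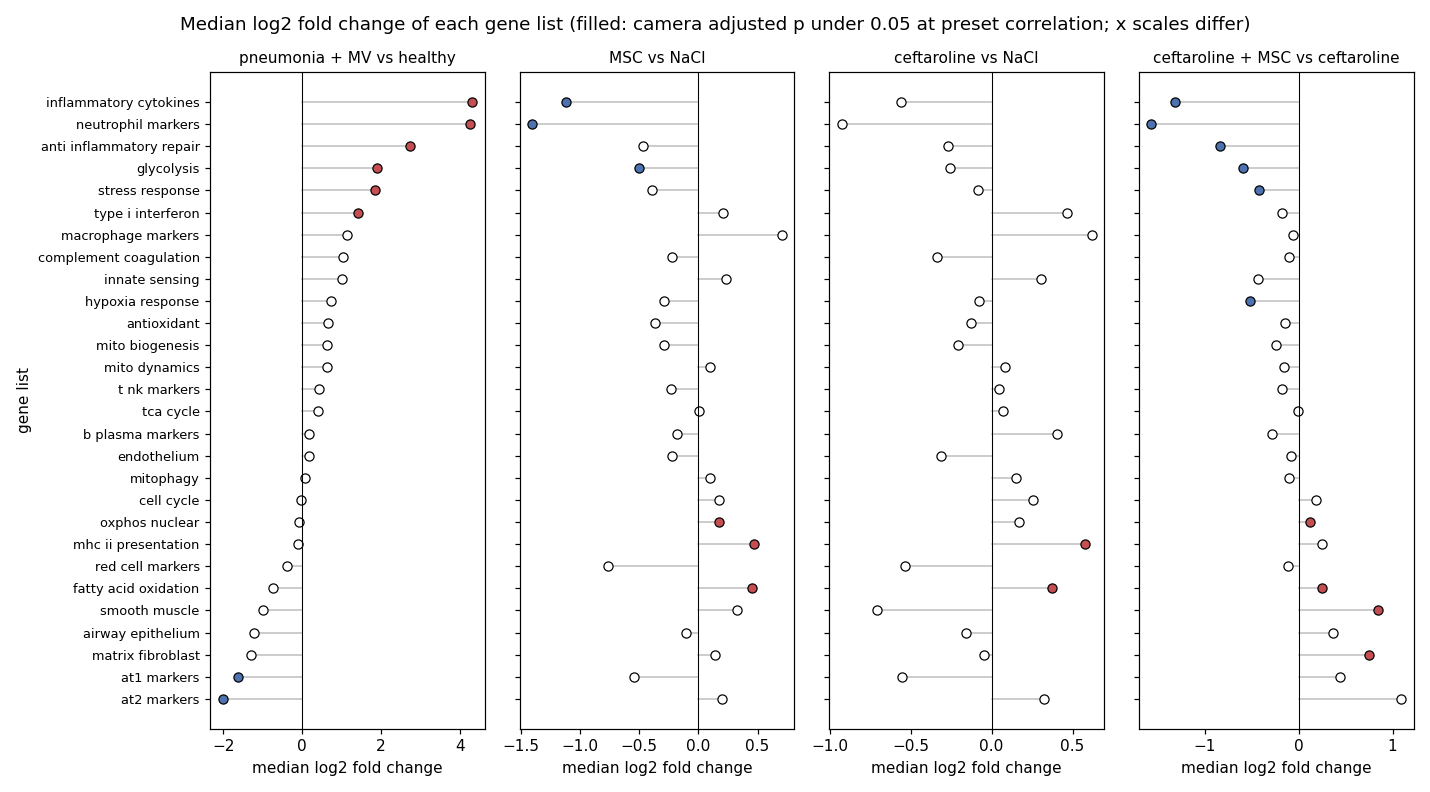
The median log2 fold change of the tested members of each gene list is plotted for the 4 comparisons, filled where camera gave an adjusted p under 0.05 with the preset correlation. Filled points number 8 for disease, 6 for MSC, 2 for ceftaroline and 10 for ceftaroline plus MSC.

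MSC were set against NaCl in rabbits with pneumonia and ventilation to ask what the cells alter in the injured lung. Inflammatory cytokine genes ranked lower with MSC, and 19 of 22 tested members had a lower mean (adjusted p = 0.000145 by camera; adjusted p = 0.832 with an estimated correlation). IL6 averaged 17344 ± 14059 normalized reads with NaCl and 3693 ± 3785 with MSC (SD, n = 7 each), a log2 fold change of -3.14 (SE 1.29) with an adjusted p of 0.234, or of -1.96 without MSC replicate 6. CAMP, the granule peptide of neutrophils, averaged 15243 ± 8981 and 3523 ± 3480 (log2 fold change -3.24, SE 0.91, adjusted p = 0.159). Genes of oxidative phosphorylation ranked higher, with 20 of 21 members above NaCl (adjusted p = 0.0196; adjusted p = 0.832 with an estimated correlation). No single gene passed the threshold in limma.

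Of 9446 genes tested, limma and edgeR called 0 each, with a lowest adjusted p of 0.159 in limma. An unadjusted p under 0.05 was reached by 1672 genes in limma and 1731 in edgeR, where 472 would be by chance. The authors' deposited table lists 336 genes, 190 higher and 146 lower, and 314 of the 315 that were also tested here had an unadjusted limma p under 0.05. In the authors' deposited table CXCL8 had an adjusted p of 0.0483. Without NaCl replicate 1 limma called 5 genes, without MSC replicate 1 it called 2, and without any 1 of NaCl replicates 2 to 7 or MSC replicate 7 it called 1. In libraries without a title ending (4 NaCl and 5 MSC) 7 genes passed. In libraries with it (3 NaCl and 2 MSC) limma called 0, with 493 genes at an unadjusted p under 0.05. The largest fall that the authors' deposited table gives was that of CFAP61, a gene of the ciliary axoneme, at -7.03, which was chosen after its values were seen. In limma CFAP61 stood at -5.21 (adjusted p = 0.159), with means of 1722 ± 1580 and 13.1 ± 8.30 (SD, n = 7 each).

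Of 28 lists tested, 3 ranked higher and 3 lower with MSC, and none of the 6 did with an estimated correlation (adjusted p = 0.832 with an estimated correlation for each). Fatty acid oxidation had 9 of 10 members higher (adjusted p = 0.0151), with ACADL, a long-chain dehydrogenase, at 0.54 (SE 0.18) and CPT2, the inner-membrane carnitine transferase, at 0.62 (SE 0.21). MHC class II presentation had 7 of 10 higher (adjusted p = 0.0348), with the transactivator CIITA at 1.18 (SE 0.37) and the peptide-loading RLA-DMB at 1.13 (SE 0.43). Neutrophil markers had 9 of 10 lower (adjusted p = 0.0172), with lactoferrin (LTF) at -2.23 (SE 0.90). All 10 glycolysis genes were lower (adjusted p = 0.0348), with HK1 at -0.61 (SE 0.30) and HK2 at -0.55 (SE 0.32; -0.31 without MSC replicate 6). NDUFB6, an accessory subunit of complex I, stood at 0.43 (SE 0.16), the feedback inhibitor of NF-kB TNFAIP3 at -1.98 (SE 0.51) and PTGS2, which makes prostaglandins, at -2.02 (SE 0.63). No member of the 6 lists passed over all genes. Adjusted over the list alone, TNFAIP3 (0.0318) and CAMP (0.0286) passed, and in lists that did not rank apart so did HSPA8, HMOX1, GCLC, CAT, MIEF1 and PDGFRB. In libraries without a title ending the lists of cytokines, neutrophils and glycolysis ranked lower, as did red cell markers, while smooth muscle ranked higher and oxidative phosphorylation, fatty acid oxidation and MHC class II had adjusted p above 0.05. Among NaCl lungs, the 3 with a title ending had median log2 differences from the other 4 of -2.07 for cytokines, -1.03 for neutrophil markers, -1.50 for glycolysis, -0.25 for oxidative phosphorylation, -0.86 for MHC class II and -0.07 for fatty acid oxidation.

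In the panel, CXCL8 had a log2 fold change of -2.58 with MSC (SE 0.94, adjusted p = 0.204), S100A8 -1.45 (SE 0.61, adjusted p = 0.245), IL1B -1.25 (SE 0.86, adjusted p = 0.470), IL10 -0.74 (SE 0.70, adjusted p = 0.612) and TNF -0.66 (SE 0.95, adjusted p = 0.757). PINK1 stood at 0.20 (SE 0.31, adjusted p = 0.770). With 1 library left out at a time, IL1B ranged from -1.66 to -0.69, IL10 from -1.14 to -0.39, TNF from -1.17 to -0.19 and PINK1 from 0.01 to 0.34. Without a title ending IL6 stood at -2.05, CXCL8 at -2.56 and PINK1 at -0.27.

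Ceftaroline was set against NaCl to ask how the antibiotic alters the lung's response. MHC class II genes ranked higher with the antibiotic, 9 of 10 members having a higher mean (adjusted p = 0.0469; adjusted p = 0.822 with an estimated correlation). CIITA, their transactivator, averaged 402 ± 235 normalized reads with NaCl and 1026 ± 504 with ceftaroline (SD, n = 7 each), a log2 fold change of 1.37 (SE 0.37, adjusted p = 0.134). All 10 fatty acid oxidation genes were higher (adjusted p = 0.0469; adjusted p = 0.822 with an estimated correlation), with ACADL at 0.52 (SE 0.18, adjusted p = 0.173) and CPT2 at 0.63 (SE 0.22, adjusted p = 0.177). IL6 averaged 21444 with NaCl and 4396 with ceftaroline, a log2 fold change of -3.17 (SE 1.19, adjusted p = 0.192). HLA-DPA1, a class II chain, stood at 0.67 (SE 0.27, adjusted p = 0.225).

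Of 9614 genes tested, limma and edgeR called 0 each, with lowest adjusted p of 0.120 and 0.102, while 1760 and 1881 genes had an unadjusted p under 0.05, where 481 would by chance. The authors' deposited table lists 501 genes, 249 higher and 252 lower, CIITA among them. The count depended on 1 library: without NaCl replicate 1, limma called 176 genes, among them CIITA at 1.58 (adjusted p = 0.0406), and without NaCl replicate 3 it called 1. All ceftaroline libraries lack a title ending, and against the 4 NaCl libraries that also lack it limma called 0, with 1666 genes at an unadjusted p under 0.05. In that comparison CIITA stood at 0.91, IL6 at -3.0 and PINK1 at -0.24.

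The 2 lists above were those past the threshold of 28, and no member passed over all genes. Adjusted over the list alone, CIITA passed (0.0227), as did 6 complement and coagulation genes, of which C1S, C1R and C2, early proteases of the classical and lectin pathways, were higher and F3, PROCR and PLAU lower. GCLC, HMOX1, SUCLG2, FCRL5 and ANXA1 passed in their lists too. Against NaCl libraries without a title ending, cytokines, neutrophil markers, glycolysis and red cell markers ranked lower, and fatty acid oxidation and MHC class II, which among NaCl lungs had a median log2 difference of -0.86 by title ending, did not pass. Panel genes stood at -1.76 for CXCL8 (SE 0.92, adjusted p = 0.324), -1.26 for S100A8 (SE 0.70, adjusted p = 0.352), -0.81 for IL1B (SE 0.82, adjusted p = 0.631), -0.29 for IL10 (SE 0.95, adjusted p = 0.901), 0.28 for TNF (SE 0.85, adjusted p = 0.892) and 0.14 for PINK1 (SE 0.30, adjusted p = 0.837). The signs of IL10, TNF and PINK1 changed between settings, and with 1 library left out at a time IL1B ranged from -1.24 to -0.37, IL10 from -1.0 to 0.08, TNF from -0.23 to 0.75 and PINK1 from 0.00217 to 0.27.

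Ceftaroline plus MSC was set against ceftaroline alone to ask what the cells add to the antibiotic. SEC62, a subunit of the channel that moves proteins into the endoplasmic reticulum (ENSOCUG00000008720), rose from 620 ± 77.9 to 1184 ± 158 normalized reads (SD, n = 7 each), a log2 fold change of 0.93 (SE 0.11, adjusted p = 0.00463). IL18R1, the receptor chain that binds interleukin 18 (ENSOCUG00000016476), fell from 145 ± 14.6 to 68.8 ± 16.1, a log2 fold change of -1.09 (SE 0.16, adjusted p = 0.0243). In the comparison of NaCl with healthy, SEC62 fell by 1.07 and IL18R1 rose by 2.22. A pair of genes without a symbol, chosen after their values were seen, also rose: ENSOCUG00000021154 by 0.62 (SE 0.08, adjusted p = 0.00830) and ENSOCUG00000027927 by 2.21 (SE 0.34, adjusted p = 0.0324).

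These were the 4 genes, 3 higher and 1 lower, that limma called of 9924 tested, with 1143 at an unadjusted p under 0.05 where 496 would be by chance. edgeR called 11, 9 higher and 2 lower, with all 4 among them. The authors' deposited table lists 108, 75 higher and 33 lower, with CXCL8 at -3.51 (adjusted p = 0.0114) and IL10 at -3.40 (adjusted p = 0.0208). After TMM scaling limma called 8, of which 87.5% were higher. The count was 2 without any 1 of ceftaroline replicates 2, 3, 5 and 7 or ceftaroline plus MSC replicates 2, 4 and 6, and IL18R1 then had an adjusted p between 0.0523 and 0.0954. SEC62 passed without any 1 library, with adjusted p from 0.00405 to 0.0220. Neither SEC62 nor IL18R1 passed with the replicate block by title number, which is described further below. The count of called genes was 6 without ceftaroline replicate 1 or 4 and 14 without ceftaroline plus MSC replicate 7. No library in these groups has a title ending.

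The lungs given both treatments did not lie together, a grouping that was seen in the data and not set beforehand. Replicates 3, 5 and 6 had log2 levels of 3.04 to 4.95 for IL6 and 8.97 to 10.39 for CXCL8, and the other 4 had 9.66 to 12.43 and 12.15 to 13.18, against means of 1.92 and 6.70 in healthy lungs. The first principal component put the same 3 lungs at -69.7 to -54.7 and the other 4 at 15.2 to 55.8. The list results of this comparison rest on means over both sets of lungs.

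Of 29 lists, 4 ranked higher and 6 lower when the cells were added, none of them with an estimated correlation (adjusted p = 0.595 with an estimated correlation for each). Smooth muscle genes were higher in 8 of 8 members (adjusted p = 0.000762), with PDGFRB, the receptor of pericytes, at 0.89 (SE 0.22) and LMOD1, which nucleates actin filaments, at 1.10 (SE 0.39). Oxidative phosphorylation had 19 of 21 higher (adjusted p = 0.00419), with the complex IV subunits COX6A1 at 0.27 (SE 0.09) and COX5B at 0.32 (SE 0.11). Fatty acid oxidation had 9 of 10 higher (adjusted p = 0.0120), with the carnitine carrier SLC25A20 at 0.26 (SE 0.13) and ACADL at 0.32 (SE 0.16). Matrix genes had 8 of 10 higher (adjusted p = 0.0120), with the collagen chains COL1A1 at 0.56 (SE 0.22) and COL1A2 at 1.36 (SE 0.54). Cytokines had 21 of 22 lower (adjusted p = 1.5e-05), with the neutrophil chemokines CXCL5 at -2.50 (SE 0.88) and CXCL8 at -2.72 (SE 0.98). Neutrophil markers had 10 of 11 lower (adjusted p = 0.00144), with myeloperoxidase (MPO) at -1.24 (SE 0.49) and the chemokine receptor CXCR1 at -1.79 (SE 0.72).

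Glycolysis had 10 of 10 members lower with the cells added (adjusted p = 0.00177), with HK2 at -0.60 (SE 0.23) and the glucose carrier SLC2A1 at -1.13 (SE 0.45). The hypoxia response had 11 of 13 lower (adjusted p = 0.0120), with DDIT4, an inhibitor of mTOR, at -1.0 (SE 0.44) and NDRG1 at -0.74 (SE 0.33). The stress response had 8 of 8 lower (adjusted p = 0.0275), with ASNS at -0.47 (SE 0.25) and the chaperone HSP90B1 at -0.40 (SE 0.23; -0.26 without ceftaroline replicate 6). Resolution and repair had 9 of 12 lower (adjusted p = 0.0367), with the growth factor AREG at -1.24 (SE 0.48) and annexin A1 (ANXA1) at -0.58 (SE 0.24). No list member passed over all genes. Adjusted over the list alone, PDGFRB, LMOD1 and ACTA2 of the smooth muscle list passed, as did GCLM and HMOX1 of the antioxidant list. Panel genes stood at -2.73 for IL6 (SE 1.69, adjusted p = 0.479), -1.91 for IL10 (SE 0.89, adjusted p = 0.432), -1.89 for IL1B (SE 0.93, adjusted p = 0.435), -1.30 for TNF (SE 0.95, adjusted p = 0.526) and 0.48 for PINK1 (SE 0.29, adjusted p = 0.479). With 1 library left out at a time IL10 ranged from -2.29 to -1.20 and TNF from -1.77 to -0.75. CXCL8 had an adjusted p of 0.416, and S100A8 stood at -1.57 (SE 0.94, adjusted p = 0.474).

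Whether the antibiotic alters the effect of MSC was asked by testing the difference between both MSC effects over 9417 genes. SEC62 had the lowest p, its MSC effect being -0.32 without and 0.93 with ceftaroline, a difference of 1.25 (SE 0.22, adjusted p = 6.7e-05 against a normal distribution). In all, 25 genes passed and 607 had an unadjusted p under 0.05. Among them were also C11orf68 (1.22, SE 0.26), AMIGO3, a leucine-rich adhesion protein (1.44, SE 0.33), MRPS12 of the mitochondrial ribosome (0.97, SE 0.23), APAF1, the scaffold of the apoptosome (-0.70, SE 0.17), and PIGK, which attaches lipid anchors to proteins (-1.41, SE 0.37), all chosen by their result. A joint limma fit of the 4 pneumonia groups called 1 gene and a joint edgeR fit 1, with 553 and 633 at an unadjusted p under 0.05. The joint edgeR fit is the form that had been named beforehand for counts of all 4 groups. The lowest adjusted p in these fits were 0.0259 and 0.0268. Title endings mark 3 NaCl and 2 MSC libraries and none with ceftaroline, so they were not matched in this test. In the panel the difference was 0.42 for IL6 and -0.14 for CXCL8, neither past the threshold.

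The treatment effects were set against the disease effect across genes, which are not independent replicates, to ask whether they run against it. The MSC effect and the disease effect had a Spearman correlation of -0.608 over 9279 genes, and the ceftaroline effect and the disease effect -0.455 over 9343 genes. Both pairs share the NaCl libraries, which alone gives negative values: simulated unchanged groups had medians of -0.476 (95% of simulations from -0.825 to 0.109) and -0.499 (-0.828 to 0.0789), and both observed values lie inside. The covariance was -0.395 for MSC and -0.288 for ceftaroline, against simulated means of -0.0524 (95% from -0.155 to 0.00938) and -0.0544 (-0.157 to 0.00569), and both lie outside. The simulated groups carried no disease effect either, and a covariance grows with that effect. Lying outside therefore does not by itself show that the treatments run against the disease. With separate NaCl libraries for each comparison the median correlation over 70 splits was -0.481 for MSC (from -0.596 to -0.0988) and -0.368 for ceftaroline (from -0.532 to 0.0233). The effects of ceftaroline and MSC had a correlation of 0.851 over 9420 genes, with a simulated median of 0.491 (95% from -0.172 to 0.840). With separate NaCl libraries the median was 0.526 (splits from -0.0214 to 0.722). Their covariance was 0.217, against a simulated mean of 0.0665 (95% from -0.0187 to 0.214). All simulated groups had equal spread, but the real ones did not. On the axis from healthy to pneumonia the SD was 0.0417 in healthy, 0.129 in NaCl, 0.257 in MSC and 0.286 in ceftaroline. The simulated values therefore need not be those that sharing the real NaCl libraries alone would give. In pairs of comparisons that share no library, the MSC effects with and without ceftaroline had a correlation of 0.491, and the disease effect and the MSC effect under ceftaroline -0.779, over 9269 genes. No simulated values were set beside these pairs. Lungs given both treatments scored from 0.156 to 0.936 on the axis from healthy to pneumonia, so an uneven draw of lungs could also give a large correlation. The exact permutation test of the score gave an adjusted p of 0.175 for ceftaroline plus MSC against ceftaroline.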

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

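Tests chosen only after the results were seen were the share of core families at 0, other splits of the libraries (also those of the NaCl libraries by title ending), TMM scaling, gene comparisons by title ending, joint interaction fits, leaving single lungs out of the score, and depth by Spearman and without 2 libraries. The joint edgeR interaction had been named beforehand for counts, but its use on recovered reads was decided later. The bound for the title ending across groups was tightened after its value was seen, and its verdict was changed from against to undecided once the endings in each group were counted. The verdicts on depth and title ending for the score were likewise changed once 95% intervals were computed. Tests of the score by permutation, by depth (Pearson) and, for MSC alone, by title ending, of neighbours and of the title ending across groups were set before their values were seen.

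Single rabbits stood apart from the rest of their group in some of the genes named. IL6 was at 8.35 normalized reads in MSC replicate 6, where the other 6 MSC lungs had 670 to 10248, a gap of 0.611 of the group's range on the log2 scale. CXCL8 in the same lung was at 322 against 4895 to 34401 (gap 0.582), and its score on the axis from healthy to pneumonia was 0.241 against 0.730 to 0.991 (gap 0.652), so this lung was the nearest to healthy of its group. S100A8 was at 54134 in NaCl replicate 5 against 184819 to 391052 (gap 0.621), RLA-DMB at 6474 in NaCl replicate 1 against 1059 to 1943 (gap 0.665), and TNF at 64.0 in ceftaroline replicate 7 against 462 to 841 (gap 0.767). Among healthy lungs, CAMP was at 1001 in replicate 7 against 31.1 to 77.4 (gap 0.740) and RTKN2 at 44.3 in the same lung against 108 to 174 (gap 0.650). CXCL8 was at 36.8 in healthy replicate 3 against 71.9 to 99.9 (gap 0.669), SLC6A2 at 3170 in healthy replicate 2 against 1042 to 1672 (gap 0.575), and IL10 at 0 in healthy replicate 6 against 2.48 to 4.66 (gap 0.719). These were 11 of 157 groups of values looked at, where about 7.85 would stand apart this far by chance, about 1 in 20. Single lungs also carry much of the group differences in score: that of MSC from NaCl went from -0.181 to -0.0928 without MSC replicate 6, and that of ceftaroline from -0.118 to -0.0342 without ceftaroline replicate 7 and to -0.0783 without its replicate 3. With both treatments, replicates 3, 5 and 6 scored 0.156, 0.274 and 0.229 and the other 4 lungs 0.699 to 0.936.

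The difference between the MSC effects with and without ceftaroline passed for 25 genes in the test on 2 separate fits, read against a normal distribution, foremost SEC62 with a difference of 1.25 on the log2 scale. Joint limma and edgeR fits called 1 gene each. Drawn splits of the libraries reached the count of 25 in 5 of 100 cases and gave up to 62 genes, so that chance cannot be excluded for it.

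Genes that every cell uses were listed at 0 in all 35 libraries, among them HNRNPK, EP300, TOP1 and IQGAP1, while GAPDH had 248892 and EEF1A1 1904610 reads in all. Of 181 genes of core families (such as ribosomal proteins, the proteasome and splicing factors), 30.9% were at 0, which argues against silence in these lungs. Around core genes at 0 the share of neighbours on the chromosome that were also at 0 was higher by 88.1 percentage points than around other core genes (92.5% against 4.40%; permutation p = 1e-04, the smallest that 10000 permutations can give), and 1 run held 153 genes in a row. A candidate explanation is that stretches of the genome were left out of the counting reference. SFTPC, SCGB1A1, MFN2, TLR4, MYD88, NLRP3 and the 13 mitochondrial genes are at 0 too, so their values say nothing about these lungs, and no biological explanation other than silence was tested.

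The means of treated groups lay nearer to healthy on the score, at 0.772 ± 0.257 with MSC, 0.835 ± 0.286 with ceftaroline and 0.558 ± 0.328 with both, against 0.953 ± 0.129 with NaCl (SD, n = 7 each). Below the NaCl mean were 5 of 7 MSC lungs but only 3 of 7 ceftaroline lungs, and 5 of 7 lungs with both were below the ceftaroline mean. Among NaCl lungs the mean was 1.04 without a title ending and 0.830 with it. Exact permutation tests of MSC against NaCl, ceftaroline against NaCl and both against ceftaroline gave adjusted p of 0.175, 0.357 and 0.175 (unadjusted 0.102, 0.357 and 0.117), so chance differences between rabbits stay open for these comparisons. Lungs given both treatments were not tested against NaCl, so these tests do not cover that gap. Without title endings the difference from NaCl was -0.194 for MSC, 1.07 times that in all libraries (95% interval -0.358 to -0.0308), and -0.210 for ceftaroline, 1.78 times (-0.477 to 0.0581), so neither shrank, but both intervals also hold far smaller differences, and the title ending stays open. The score's correlation with log2 total reads inside the 28 pneumonia libraries, each group centred, was 0.0150 (Pearson, 95% interval -0.382 to 0.408, permutation p = 0.949) and -0.128 (Spearman, permutation p = 0.546), and -0.0806 without ceftaroline replicates 4 and 5, an interval too wide to exclude depth. An effect of the treatments may underlie the order of the groups, but these tests leave it open.

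The 3 NaCl libraries with a title ending (replicates 5, 6 and 7) lay apart from the other 4 on the second principal component, at -75.5 to -59.9 against -26.4 to 16.8. Their titles also begin with other letters (I or L, against B), as do those of the MSC libraries with the ending (N, against C). In these groups the ending cannot be told apart from what the first letter marks. With the preset correlation, interferon-induced genes (median log2 difference -1.87, adjusted p = 1.2e-10), cytokines (-2.07, 4.7e-06), glycolysis (-1.50, 3.1e-06), MHC class II (-0.86, 0.000375), red cell markers (-2.64, 0.000244) and oxidative phosphorylation (-0.25, 0.00203) ranked lower in them and smooth muscle genes (2.56, 1.6e-05) higher, other lists passed too, and none did with an estimated correlation (lowest adjusted p = 0.385). The real split gave 3432 genes at an unadjusted p under 0.05, which 1 of 35 splits reached, with 2278 as the highest other, but this was counted on the libraries in which the separation had been seen and is no independent evidence against chance. The same difference had a Spearman correlation across genes of -0.101 in healthy lungs and of 0.616 in MSC lungs (1 of 21 splits, highest other 0.403). Healthy lungs carry 4 PD and 1 PG endings and the NaCl and MSC lungs PG alone, so the healthy value decides nothing about PG, and a sampling difference that PG names stays open, with the meaning of both endings not given in the sources used here and no biological explanation tested.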

How the results depend on the processing

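Alternatives by title ending, edgeR, TMM scaling, joint interaction fits, split NaCl libraries and list tests with the block, the ending or the S00 library were chosen only after the data were seen. An exception in part is the joint edgeR interaction, which had been named beforehand for counts and was run here on recovered reads.

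Named genes kept direction and side of the threshold in 2651 alternative values, lost the threshold in 36 and gained it in 27. The direction reversed in 22, all of genes that pass neither way. PINK1 was at -0.27 with MSC and -0.24 with ceftaroline in libraries without a title ending. With ceftaroline, TNF was at -0.57 and IL10 at 0.84 in the authors' deposited test and at -0.56 and 0.82 in edgeR, and TNF at -1.06 without title endings. Over single libraries left out TNF ranged from -0.23 to 0.75 and IL10 from -1.0 to 0.0806. In disease, 23 genes lost the threshold with the empirical null, and RTKN2 also in libraries with a title ending. Of the answers to the comparisons, 104 alternative values stayed within the bounds set and 58 moved. Where no cause is given, the cause was not tested.

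By construction, a log2 fold change of at least 1 lowered the disease count to 3400 and that of ceftaroline plus MSC to 2, and thresholds of 0.01 and 0.1 gave 2 and 23 for the latter and 41 at 0.1 for the interaction. With the replicate block by title number, limma called 0 genes for ceftaroline plus MSC (1297 at an unadjusted p under 0.05), with SEC62 and IL18R1 at an adjusted p of 0.193, 0 for MSC (1560) and 0 for ceftaroline (1423), and camera called 4 lists for ceftaroline. The numbers did not clearly pair the lungs: profiles of same-numbered lungs correlated above 0.1 in 3, 2 and 4 of 7 pairs, and 4, 2 and 1 of 14 lungs correlated best with their own number. Between NaCl and MSC the mean correlation was 0.109 for the same number and -0.0186 for other numbers. It was -0.0465 and 0.00758 between NaCl and ceftaroline, and 0.0810 and -0.0130 between ceftaroline and both treatments. These means were not tested, so a pairing stays open. The block also leaves fewer degrees of freedom.

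The authors' deposited test gave 336, 501 and 108 genes for MSC, ceftaroline and ceftaroline plus MSC. Adjusted over every gene with a p these were 250, 413 and 101, over means of at least 10 they were 334, 500 and 110, and over means of at least 50 they were 280, 472 and 88. Against a t distribution with 12 degrees of freedom it gave 1 for MSC, 0 for ceftaroline and 2 for ceftaroline plus MSC, so the normal reference accounts for most of these calls. Scaled to an empirical null, it gave 111 genes in disease and 1 for MSC; where most genes change, that null absorbs the effect.

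edgeR called 11 genes and TMM scaling 8 for ceftaroline plus MSC, and 1 gene passed for MSC with no filter. Joint limma and edgeR fits called 1 gene each for the interaction, in place of 25. Libraries without a title ending gave 3764 genes in disease and 7 for MSC, with 13 lists in disease and 4 for ceftaroline, from fewer lungs. Without the S00 library 6 lists passed for ceftaroline. With an estimated correlation camera called 0 lists in disease, 0 for MSC, 0 for ceftaroline and 0 for ceftaroline plus MSC, where the preset correlation gave 8, 6, 2 and 10. With split NaCl libraries the correlation of disease and MSC effects was -0.481 in place of -0.608 and that of both treatments 0.526 in place of 0.851, where the comparisons share no NaCl library but also have fewer of them, and these causes were not tested apart.

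Leaving out 1 library at a time gave 5471 to 5862 genes in disease, 0 to 5 for MSC, 0 to 176 for ceftaroline and 2 to 14 for ceftaroline plus MSC. The highest came without NaCl replicate 1 for both single treatments and without ceftaroline plus MSC replicate 7 for the last. At a log2 change of 1, simulated data at this depth and number of lungs gave 13 of 50 changed genes for MSC, 17 for ceftaroline and 21 for ceftaroline plus MSC, so changes of that size were mostly not detectable.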

Other observations

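All tests and comparisons in this part were chosen after the data were seen, except the panel of genes and the gene lists.

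SEC62 and IL18R1, the called genes with a symbol when MSC were added to ceftaroline, moved the other way in disease, SEC62 at -1.07 and IL18R1 at 2.22. SEC62 stood at -0.32 with MSC alone and at -0.28 with ceftaroline alone. PPARGC1A, the coactivator under the minimum for testing, had 67 reads in the 7 healthy lungs, 26 with NaCl, 52 with MSC, 74 with ceftaroline and 55 with both, with no test made. These sums are not scaled for depth and do not give an order of levels. In the same order, the median of total reads per library was 9731971, 9527492, 10577412, 15675806 and 12927861. With MSC the authors' deposited table gives GSG1 at 4.85 among the largest rises, a gene under the minimum for testing in limma. With ceftaroline the authors' deposited table gives GSG1 at 5.04 and the acyl-CoA synthetase ACSM3 at 3.33, and falls of ANKRD1 at -3.33 and the hyaluronan synthase HAS2 at -3.06. In limma GSG1 was again not tested, and the others did not pass. ACSM3 stood there at 2.25 (adjusted p = 0.156), ANKRD1 at -3.40 (adjusted p = 0.121) and HAS2 at -2.72 (adjusted p = 0.124). With MSC added to ceftaroline the authors' deposited table gives PPP1R14A, an inhibitor of myosin phosphatase, at 1.86. In limma this gene stood at 2.06 and did not pass (adjusted p = 0.114).

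Alveolar and airway genes leaned upward with ceftaroline plus MSC against ceftaroline, with 8 of 8 type I markers, 3 of 3 type II markers and 10 of 10 airway genes higher, and list tests at adjusted p of 0.202, 0.217 and 0.215. SLC34A2 had a mean log2 level of 12.31 with both treatments and of about 11 with ceftaroline (n = 7 each), and of 14.35 in healthy lungs. In the combined group it stood at 14.31 to 14.39 in replicates 3, 5 and 6 and at 9.42 to 11.64 in the other 4, and with ceftaroline alone from 7.71 to 14.36, so the means stand for spread-out lungs.

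Genes at an unadjusted p under 0.05 in both the disease and the MSC comparison numbered 1292 in opposite directions (633 higher then lower, 659 lower then higher, where independence would give 243 and 281) and 30 in the same. For ceftaroline these were 1203 (595 and 608, where independence would give 253 and 291) and 76. For ceftaroline and MSC, 1039 genes went in the same direction, 598 higher and 441 lower, where independence would give 89.3 and 64.8. The shared NaCl libraries add to the opposite-direction numbers of disease against treatment and to the same-direction numbers of ceftaroline and MSC. They lower the same-direction numbers of 30 and 76.

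Other splits of the 14 libraries of each comparison were tested, 100 with the real one included. The 5788 genes called between NaCl and healthy were reached by 1 split, the real one, with 3192 as the highest other, so that chance can be excluded. Genes at an unadjusted p under 0.05 with MSC (1672) were reached by 3 splits, with 2521 as the highest other, and with ceftaroline (1760) by 2 splits, with 1867 as the highest other. By share alone this argues against chance, but other splits gave more genes, none passed adjustment in the real one, and the exact tests of the score leave chance open, so it is not taken as excluded. For ceftaroline plus MSC the 4 called genes were reached by 2 splits, but the 1143 genes at an unadjusted p under 0.05 by 10, with 2740 as the highest other, so chance is not taken as excluded there either. Other splits called up to 694 genes in that comparison and up to 621 in that of MSC, many more than the real ones, which points to a structure of the samples that the treatments do not follow. For counts of lists chance cannot be excluded: 8 in disease (reached by 42 splits, highest other 16), 6 with MSC (68 splits, highest other 15), 2 with ceftaroline (95 splits, highest other 16) and 10 with ceftaroline plus MSC (33 splits, highest other 16). Chance differences between lungs may thus give as many lists as the treatments do.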
